A study of Caenorhabditis elegans with 12 samples.

How the data were processed

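Gene expression was measured by RNA sequencing of total RNA from whole hermaphrodites, 1 library per sample, in 12 samples. Libraries were made with the TruSeq RNA Library Preparation Kit v2, per the labels' protocols. The deposited counts are whole numbers per gene and library, for which the submitters' processing notes name bcl2fastq 1.8.4, STAR 2.4.1d, featureCounts 1.4.6-p4 and the genome build WBcel235. The deposited RPKM values were scaled by the authors per kilobase of gene and by a per-million factor of reads, and the processing notes name the same tools for them. The notes do not give the annotation release, the strand setting or the handling of reads that map to several places. Values of near-identical paralogs (such as C-type lectin, collagen, major sperm protein and histone genes) and of overlapping or antisense genes are therefore uncertain.

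Samples were grouped by strain and bacterial feeding as the labels give them, 3 per group. The labels name libraries by number, from 1 to 6 in daf-16(mu86) and from 7 to 12 in TU3311, with vector and RNAi libraries in turn, and the replicates of each group are numbered here in that order. The titles and the descriptions of the first 6 libraries give different run names, which were not needed to join labels and values.

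The RPKM values were checked against the counts. Over 125490 values with a count of at least 100, the per-million factor changed from gene to gene within a library, in a sequence of 36 factors that repeated down the table. The log2 SD within a gene was 7.19e-05 around that sequence and 0.228 around 1 factor per library. RPKM values of different libraries are therefore not on 1 scale, and they were used only for this check and for alternatives, named as RPKM or part of the ranges over other settings, while all other values rest on the counts.

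The main test was the quasi-likelihood F test of edgeR 4.0.16 (limma 3.58.1, R 4.3.3), two-sided, with robust dispersion, TMM factors, the default expression filter by group and all 4 groups in 1 fit, which left 8 residual degrees of freedom. Of 46748 gene identifiers 16618 were tested. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called, and the counts at a change of at least 2-fold are given beside them. The same fit gave 3 comparisons of groups and the difference between the responses to the labelled RNAi. Values in CPM are TMM-scaled counts-per-million, and log2 CPM used a prior count of 2. Every adjusted p of a gene is from edgeR unless another tool is named. The SE given after ± with a log2 change of a gene was computed back from the edgeR test. It is the absolute change over the square root of F, and so no measure of spread apart from the p.

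Gene lists, 42 in number, were tested with camera of limma on voom values with a preset correlation of 0.01 between genes, adjusted over the lists of a comparison. Camera compares the members with the other genes, so a list called higher or lower is so against them and not against 0. Camera with an estimated correlation is given beside it. Of the list entries, 9 had no match, and lists with at least 5 tested members were used. Resemblance of the responses was tested by an exact permutation of vector and RNAi labels within each strain, and later within neighbouring pairs. Names and coordinates come from an annotation of release 115, which held 46449 of the identifiers and lacked 299, and 45627 had a name.

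The genes named are, first, the 4 that the labels name. For each RNAi comparison they are the 10 rising and 10 falling genes with the largest log2 change among those called, with a mean of at least 2 CPM over the 6 libraries and no overlap between the 3 and the 3, which chance gives for 10% of genes. For the strain comparison and the difference the number is 5 each, without the overlap condition for the difference. Then come up to 4 members of each called list with the smallest p, up to 2 members past the gene test of other lists, and up to 10 genes called in both RNAi comparisons in each direction. Where none passed, the 5 genes with the smallest p in each direction are given and said not to pass. The groups, tests, lists, this rule and the alternatives were fixed before the data were examined, except for the alternatives named as added later.

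Whether neighbouring library numbers pair the samples was checked on the values, since the labels do not state a pairing. The deviations from group means correlated at 0.398, 0.284 and 0.158 in the pairs of daf-16(mu86) and at 0.892, 0.777 and 0.504 in those of TU3311, each over 0.1. Among the libraries of its strain, every library correlated best with its own neighbour. Libraries of the other strain were not compared. The pairing therefore comes from the values and not from the labels. Values with the pair as a block are given beside a result where they change a call or move a count by over 1.5 times. Pairs lie within strains, so the strain comparison has no such value.

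The steps were tested on simulated data with 50 genes changed at each of 4 fold sizes among 16618. The changed genes were drawn only from those with a mean of at least 1 CPM. The recovery given below therefore does not cover tested genes of lower level. Each gene was drawn independently around its fitted means, with pair effects kept only in the simulation of the block. Shifts shared by many genes within a library, as in libraries 7 and 8, were not simulated. The rates that follow therefore do not measure false calls from such shifts in the real libraries. In the comparison labelled bcat-1 RNAi the edgeR fit recovered 0% of 1.5-fold, 18% of 2-fold, 82% of 4-fold and 96% of 8-fold changes, with 3 false among 101 calls. With the block it recovered 44%, 80%, 100% and 100%, with 13 false among 175 calls. For the comparison labelled daf-7 RNAi these were 0%, 18%, 90% and 96% with 7 false among 109 calls, and with the block 50%, 78%, 100% and 100% with 20 false among 184. For the strain comparison they were 0%, 14%, 86% and 96%, with 4 false among 102 calls. DESeq2 gave 20 false among 126, 27 among 151 and 22 among 138 calls in the 3 comparisons, and limma-voom 2 among 99, 6 among 107 and 5 among 100.

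The alternatives were DESeq2 1.42.0, limma-voom, RLE and upper-quartile factors, library totals alone, no filter on low counts, a filter of 10 CPM in 3 libraries, only the 6 libraries of a comparison, and the block. Further ones were limma on log2(RPKM + 1) and log2(RPKM + 0.1) with a mean RPKM of at least 1 and on the first without a filter, the tests without the target, mitochondrial and ribosomal RNA genes, and leaving out each library, for genes and for lists. Leaving out libraries 7 and 8 together, and the 6 libraries with the block, were added after the data were seen. Splits of the libraries into other groups were counted as 10 per comparison and as 100 drawn of 200 for the difference. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used for tables and figures. Ribosomal RNA held 0.106 to 3.23% of counts per library, and TMM factors ran from 0.863 to 1.19.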

Results

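RNA was sequenced from whole Caenorhabditis elegans hermaphrodites aged 5 days, in 12 libraries that form 4 groups of 3. The first pair of groups is the strain CF1038, which carries daf-16(mu86), a deletion in the gene of the FOXO transcription factor that acts downstream of insulin signalling. Its animals were fed bacteria labelled with RNAi against bcat-1, the branched-chain amino acid aminotransferase, or with the empty vector L4440. The second pair of groups is TU3311, a strain whose sid-1 transgene makes neurons sensitive to fed double-stranded RNA. Its animals were fed bacteria labelled with RNAi against daf-7, the TGF-beta ligand of the dauer pathway, or the same empty vector. Libraries held 30130249 to 45343624 counts assigned to genes, and 13542 to 16809 genes with at least 10 counts. The labels do not say whether the 3 libraries of a group came from separate cultures, so every p-value measures only the spread between these libraries, which may be technical.

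The first principal component of log2 CPM (counts-per-million) held 54.9% of the variance and the second held 14.3%. The TU3311 libraries numbered 7 (vector replicate 1) and 8 (labelled daf-7 RNAi, replicate 1) stood together and apart from the other 4 of that strain. Within groups, log2 CPM of 2 libraries correlated at 0.959 to 0.992 across genes, the lowest values being those of libraries 7 and 8 with their own groups.

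**Figure D1:**
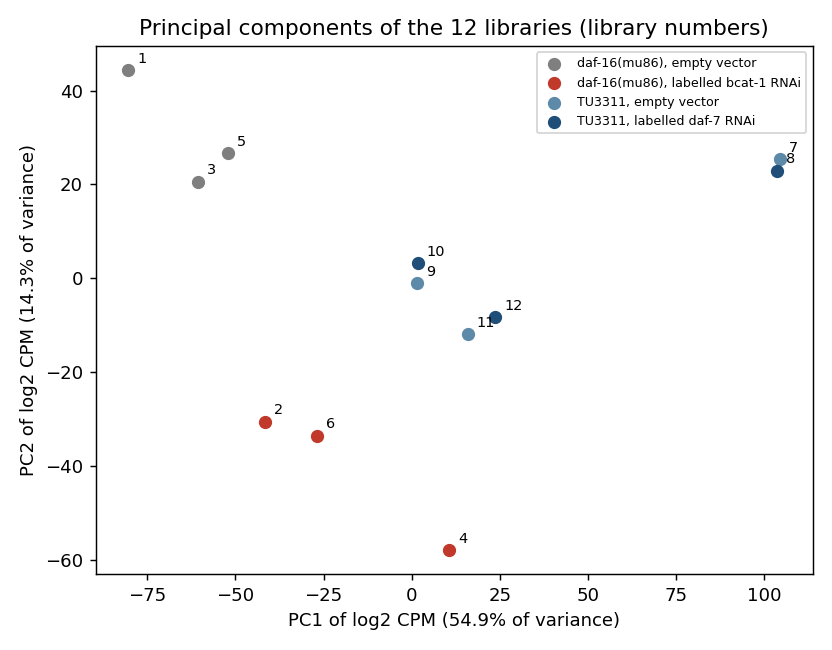
First and second principal components of log2 CPM in the 12 libraries, 1 point per library with its library number, coloured by group (3 libraries each), with the share of variance on each axis. Libraries 7 and 8, of different treatments, lie at 104.6 and 103.8 on the first component, while the other 4 TU3311 libraries lie between 1.64 and 23.7.

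The genes named in the labels were examined first, since they check the labels. bcat-1 (WBGene00001149, WBcel235 chromosome X, 12877480 to 12880328, plus strand) was not lower in the libraries labelled with its RNAi. It stood at 199 ± 29.6 CPM (SD, n = 3) there and at 140 ± 10.2 CPM in the daf-16(mu86) vector libraries, a log2 difference of 0.51 ± 0.23 (SE) that did not pass the threshold (edgeR adjusted p = 0.212). With neighbouring library numbers as a block the difference passed (adjusted p = 0.00785), and over the 14 other settings run the adjusted p ranged from 0.00411 to 0.516. In TU3311 bcat-1 stood at 190 ± 45.7 CPM on vector and 177 ± 30.2 CPM in the libraries labelled daf-7 RNAi. daf-7 (WBGene00000903, chromosome III, 811844 to 813773, plus strand) was also not lower in the libraries labelled with its RNAi. It stood at 94.5 ± 55.6 CPM there, with single values of 115, 31.4 and 137 CPM, and at 8.89 ± 2.97 CPM in the TU3311 vector libraries. That log2 difference of 3.41 ± 0.46 missed the threshold (adjusted p = 0.0556; range over 14 other settings 1.23e-11 to 1). In daf-16(mu86), daf-7 stood at 1.96 ± 0.535 CPM on vector and 3.48 ± 0.226 CPM in the libraries labelled bcat-1 RNAi. Neither target gene was thus lower where the labels name its RNAi, which by itself does not show the labels to be wrong. Every direction that follows is drawn from the labels as they stand. The counts are per gene and cover all its exons, so they do not separate transcripts of the animals from reads of the fed RNA.

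daf-16 (WBGene00000912, chromosome I, 10750498 to 10776703, plus strand) stood at 83.5 ± 5.42 CPM in the daf-16(mu86) vector libraries and 195 ± 12.7 CPM in the TU3311 vector libraries (SD, n = 3). The log2 difference of -1.23 ± 0.19 passed the threshold (adjusted p = 0.00581), except without daf-16(mu86) vector replicate 1, where the adjusted p was 0.0700 (range over 13 other settings 5.48e-04 to 0.0700). Gene-level counts do not separate the exons deleted in daf-16(mu86) from those kept, so this checks the strain labels only in part. sid-1 (WBGene00004795, chromosome V, 5119970 to 5126916, plus strand) stood at 121 ± 3.02 CPM in the daf-16(mu86) vector libraries and 203 ± 41.4 CPM in those of TU3311, which missed the threshold (adjusted p = 0.0520).

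**Figure D2:**
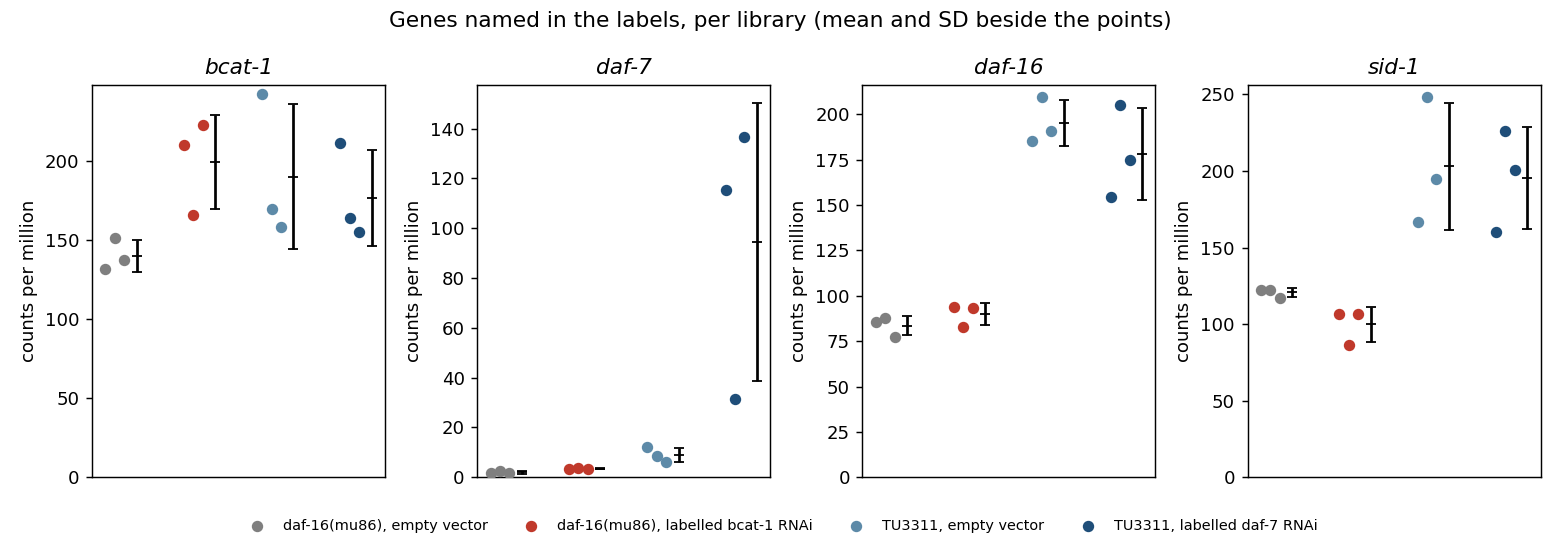
CPM (linear axes from 0) of bcat-1, daf-7, daf-16 and sid-1 in each of the 12 libraries, 1 point per library, with the mean and SD of each group (n = 3) beside the points. The 3 libraries labelled daf-7 RNAi hold 31.4 to 137 CPM of daf-7, above the 6.21 to 12.08 CPM of the TU3311 vector libraries.

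The comparison of libraries labelled bcat-1 RNAi with vector libraries in daf-16(mu86) asks how transcript levels differ under bcat-1 RNAi in animals with the daf-16 deletion. Most genes called were higher in the libraries labelled bcat-1 RNAi, and those with the largest changes are given first. cpr-2, a cathepsin B-like cysteine protease gene (WBGene00000782), rose from 0.528 ± 0.206 to 8.42 ± 3.16 CPM (SD, n = 3; log2 4.00 ± 0.52, adjusted p = 0.00246). agr-1, the agrin homologue (WBGene00018304), rose 6.94-fold from 6.68 ± 0.779 to 46.4 ± 12.5 CPM (log2 2.80 ± 0.27, adjusted p = 5.26e-04). nlp-66, a neuropeptide-like gene (WBGene00011141), rose 8.95-fold (log2 3.16 ± 0.36, adjusted p = 0.00108), and cnd-1, a NeuroD-family transcription factor gene, rose by 2.71 ± 0.36. Other large rises were those of C05E7.3 (3.01 ± 0.29), C30A5.10 (2.95 ± 0.30), Y50E8A.5 (2.90 ± 0.35), C05C12.1 (2.88 ± 0.31), C02E7.10 (3.23 ± 0.72) and the C-type lectin gene clec-47 (3.23 ± 0.60).

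Fewer genes were lower in the libraries labelled bcat-1 RNAi. far-3, a fatty acid and retinol binding protein gene (WBGene00001387), fell from 133 ± 65.4 to 16.3 ± 2.25 CPM (SD, n = 3; log2 -3.03 ± 0.73, adjusted p = 0.0384). dod-22 (WBGene00010125), known as a gene repressed by DAF-16 and a marker of the PMK-1 immune pathway, fell from 15.3 ± 4.07 to 4.24 ± 0.605 CPM (log2 -1.85 ± 0.27, adjusted p = 0.00437). The C-type lectin gene clec-74 (-2.58 ± 0.44), the infection response gene irg-5 (-2.199 ± 0.45), the epidermal antimicrobial peptide gene cnc-2 (-2.21 ± 0.53) and the inositol transporter gene hmit-1.1 (-2.81 ± 0.57) fell as well. So did srlf-34 (-2.76 ± 0.65), C45B2.1 (-2.37 ± 0.53), the astacin protease gene nas-11 (-2.19 ± 0.51) and drd-50 (-1.79 ± 0.36). dod-22 and irg-5 were the 2 of 12 PMK-1-dependent genes that fell, also adjusted over the list alone. That list was not called (adjusted p = 0.0571, estimated correlation 0.586), and its median of -0.06 turned to 0.11 and 0.15 with upper-quartile factors and library totals. Of the 10 falling genes named here, clec-74 passed the threshold in 13 of 14 other settings, dod-22 in 12, and the other 8 in 5 to 8. Of the 10 rising genes named above, 8 passed in every other setting that tested them, clec-47 in 10 of 14 and C02E7.10 in 8 of 14.

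By edgeR, 694 of 16618 genes were higher and 24 lower in the libraries labelled bcat-1 RNAi. At an absolute log2 change of at least 1 these were 647 and 22, and 3613 genes had an unadjusted p under 0.05. Measures of whole libraries also differed between these groups without overlap. Genes with at least 10 counts numbered 13542 to 14693 on vector and 15468 to 16028 in the libraries labelled bcat-1 RNAi, non-coding RNA held 0.104 to 0.134% and 0.197 to 0.233% of counts, and TMM factors were 0.863 to 0.899 and 0.966 to 1.06. Total counts overlapped. With neighbouring numbers as a block, 4275 genes were higher and 3081 lower, with all 718 called genes kept. Without libraries 7 and 8 the counts were 3455 and 2441, and with only the 6 libraries of the comparison 3628 and 2488. Libraries 7 and 8 are not in this comparison. They enter its test only through the spread, expression filter and scaling factors that all libraries share. The main counts are thus lower than those of fits in which libraries 7 and 8 have no part. Leaving out 1 library lowered the counts in each case. The numbers of higher and lower genes were 42 and 3 without vector replicate 1, 66 and 5 without vector replicate 2, 184 and 7 without vector replicate 3, 319 and 5 without RNAi replicate 1, 158 and 6 without RNAi replicate 2, and 284 and 8 without RNAi replicate 3.

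By camera with a preset correlation 6 lists were higher in the libraries labelled bcat-1 RNAi (adjusted p from 1.45e-07 to 0.00906), a call that none kept with an estimated correlation (adjusted p = 0.586 to 0.806). Of 55 neuropeptide genes, 3 rose over all genes tested and 3 adjusted over the list alone (median log2 0.67), among them flp-15 (1.34 ± 0.24) and flp-25 (1.57 ± 0.31). Of 29 synaptic and neurotransmitter genes, 2 rose and 4 adjusted over the list alone (median 0.72). They were unc-10, the presynaptic RIM protein gene (1.45 ± 0.26, adjusted p = 0.00988), and eat-4, the vesicular glutamate transporter gene (1.31 ± 0.32). Of 32 insulin-like peptide genes, 3 rose (ins-2, 2.33 ± 0.50; ins-3, 1.202 ± 0.26; ins-35, 1.93 ± 0.50) and 8 adjusted over the list alone (median 0.80). Of 208 nuclear hormone receptor genes, 12 rose and 31 adjusted over the list alone (median 0.48), among them nhr-91 (1.33 ± 0.26) and nhr-179 (1.46 ± 0.29). Of 151 cuticle collagen genes, 6 rose, while 15 rose and 3 fell adjusted over the list alone (median 1.54), with sqt-3 (1.79 ± 0.34), dpy-14 (1.96 ± 0.39) and dpy-17 (1.70 ± 0.39) among them. The collagen median depended on 1 library, bcat-1 RNAi replicate 2. From the mean of the 12 libraries the collagens stood at -1.16, -0.10 and -1.49 log2 units on vector and at -0.97, 1.42 and -0.45 in the libraries labelled RNAi. Without that library their median was 0.15 and the list was not called (adjusted p = 0.948), nor was it without vector replicate 3 (median 1.49, adjusted p = 0.102). None of the 12 mitochondrially encoded genes passed (median 0.59), nor did any adjusted over the list alone. With the block, 44 neuropeptide, 21 synaptic, 16 insulin-like, 95 receptor, 95 collagen and 10 mitochondrially encoded genes rose. With only the 6 libraries of the comparison and no block, 47, 21, 15, 88, 18 and 8 rose, against 0, 1, 1, 7, 1 and 0 that fell.

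By the same set test 14 lists were lower, and none kept its call with an estimated correlation (adjusted p = 0.586 to 0.806). None of 25 oocyte and eggshell genes passed (median log2 -0.66; chs-1, the eggshell chitin synthase gene, -0.94 ± 0.39, adjusted p = 0.183, with the block 3.23e-04), nor did any of 30 germline proliferation and P granule genes (median -0.56; fbf-2, -0.86 ± 0.23, adjusted p = 0.0546, with the block 9.17e-04) or 33 proteasome genes (median -0.45). None of these 3 lists had a member past the threshold adjusted over the list alone. With the block, 23 oocyte, 26 germline and 33 proteasome genes fell. With only the 6 libraries of the comparison and no block, 23, 25 and 32 fell, and none rose in either fit. Of 14 epidermal antimicrobial peptide genes, cnc-2 fell and 9 fell adjusted over the list alone (median -1.43; nlp-29, -1.64 ± 0.51, adjusted p = 0.0818, with the block 0.00317). With the block 11 of them fell, and with only the 6 libraries 7 fell. From the mean of the 12 libraries this list stood at 0.59, 0.10 and 0.11 log2 units on vector. In the libraries labelled RNAi it stood at -1.57, -1.49 and -0.18, so replicate 3 differed least. Metabolic and signalling lists had medians nearer 0, and 5 of them had no gene past the test, also adjusted over the list alone. These were glycolysis (22 genes, median -0.36), the TCA cycle (22, -0.25), the TOR pathway (12, -0.40), insulin signalling (10, -0.38) and the mitochondrial unfolded protein response (12, -0.23; hsp-6, -0.77 ± 0.31, adjusted p = 0.170, with the block 0.00384). Of 24 branched-chain amino acid degradation genes (median -0.35), acdh-2, an acyl-CoA dehydrogenase gene, rose (1.84 ± 0.41, adjusted p = 0.0261), also adjusted over the list alone. Of 39 RNAi and small RNA genes (median -0.27), rrf-2, an RNA-dependent RNA polymerase gene, rose (0.99 ± 0.25, adjusted p = 0.0388), also adjusted over the list alone. With the block the genes that fell, with those that rose in parentheses, were 12 (2) of glycolysis, 9 (1) of the TCA cycle, 10 (1) of the TOR pathway, 5 (0) of insulin signalling, 5 (2) of the mitochondrial unfolded protein response, 12 (2) of branched-chain amino acid degradation and 17 (1) of RNAi and small RNA genes. With only the 6 libraries these were, in the same order, 12 (2), 8 (1), 10 (1), 6 (0), 5 (2), 12 (3) and 15 (1).

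In 3 further lists called lower, which means lower than the other genes, the sign of the median depended on the scaling. The median of 51 autophagy and lysosome genes was -0.11 and turned to 0.03 and 0.08 with upper-quartile factors and library totals. That of 36 oxidative phosphorylation genes was -0.17 and turned to 0.04 with library totals. That of 32 lipase and fatty acid oxidation genes was -0.13 with a mean of -0.01 and turned to 0.02 and 0.07 with upper-quartile factors and library totals. In this list 2 lysosomal lipase genes rose, lipl-3 (2.45 ± 0.61) and lipl-1 (1.51 ± 0.39), and adjusted over the list alone 4 rose and 2 fell. Its call was lost with the block (adjusted p = 0.0811) and without vector replicate 3 (0.0701) or RNAi replicate 3 (0.179). The scalings moved the median change of all genes by -0.20 (RLE), 0.15 (upper quartile) and 0.20 (totals) from 0.16 here, by 0.21, -0.33 and -0.28 in the strain comparison, and by -0.20, 0.17 and 0.22 in the difference between the responses.

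Lists that did not pass held single genes that did. Of 138 C-type lectin genes 11 rose and 2 fell (19 and 2 adjusted over the list alone; list adjusted p = 0.103). Of 21 intestinal genes 3 rose, also adjusted over the list alone, among them the cathepsin B-like protease genes cpr-1 (1.43 ± 0.27) and cpr-5 (1.42 ± 0.25; list adjusted p = 0.301). his-71 (0.99 ± 0.21), the saposin-like gene spp-4 (1.16 ± 0.28), ugt-36 (2.08 ± 0.44) and dhs-16 (1.14 ± 0.27) rose, and the lysozyme gene lys-10 fell (-1.65 ± 0.43). Among the markers of other tissues and stages, 44 embryonic genes (median 0.37), 71 sperm genes (1.0999) and 25 muscle genes (0.13, or -0.07 with RLE factors) had no member past the test, and 2 muscle genes rose adjusted over the list alone. Their lists were not called (adjusted p = 0.655, 0.338 and 0.976), and with the block the sperm list was (adjusted p = 0.00942), as was the histone list (adjusted p = 0.0407). Sperm genes differed mainly in replicate 2. From the mean of the 12 libraries they stood at -1.60, -1.02 and -0.43 log2 units on vector and at -1.44, 0.75 and -0.42 in the libraries labelled bcat-1 RNAi.

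**Figure D3:**
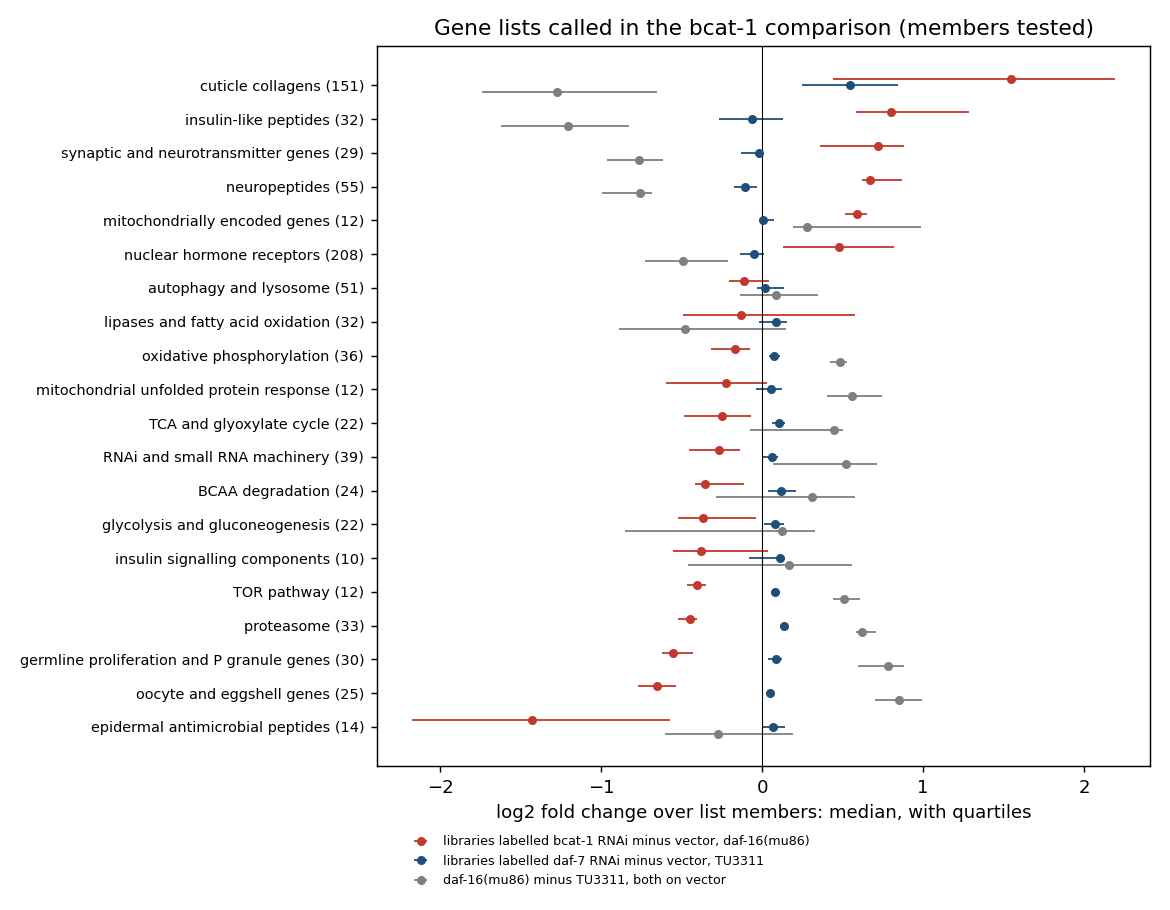
Median log2 fold change, with quartiles, over the members of the 20 gene lists called in the bcat-1 comparison, drawn for that comparison, the daf-7 comparison and the strain comparison (members tested in parentheses). In the libraries labelled bcat-1 RNAi the oocyte list lay at -0.66 and the neuropeptide list at 0.67, while the autophagy and lipase medians changed sign with upper-quartile factors or library totals and that of oxidative phosphorylation with library totals.

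The comparison of libraries labelled daf-7 RNAi with vector libraries in TU3311 asks how transcript levels differ under daf-7 RNAi in animals with RNAi-sensitive neurons. No gene passed the threshold. The gene with the smallest p was daf-7 itself, described above, at 8.89 ± 2.97 and 94.5 ± 55.6 CPM. lips-11, a lipase-family gene (WBGene00020472, chromosome II, 1108841 to 1111001, minus strand), stood at 102 ± 60.1 CPM on vector and 21.3 ± 16.7 CPM in the libraries labelled daf-7 RNAi (SD, n = 3; log2 -2.26 ± 0.49, adjusted p = 1). It was lower in the library labelled RNAi in all 3 neighbouring pairs. With neighbouring numbers as a block lips-11 passed (log2 -2.40, adjusted p = 1.80e-04; range over 14 other settings 1.80e-04 to 1), and it passed without libraries 7 and 8 (adjusted p = 0.00293), but it did not pass when the same block was fitted to only the 6 libraries, which called 0 genes. ugt-4, a UDP-glucuronosyltransferase gene, stood at 8.10 ± 1.76 and 2.98 ± 0.215 CPM (log2 -1.44 ± 0.24, adjusted p = 0.256). The other genes with the smallest p were pud-3 (1.56 ± 0.48), the saposin-like genes spp-4 (0.88 ± 0.27) and spp-23 (1.04 ± 0.32), grl-23 (2.31 ± 0.77), clec-31 (-1.61 ± 0.34), C17B7.4 (-1.92 ± 0.46) and C10C5.3 (-0.94 ± 0.26), each with an adjusted p of 1.

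By edgeR, 0 of 16618 genes were higher and 0 lower in the libraries labelled daf-7 RNAi, and 77 genes had an unadjusted p under 0.05. DESeq2 called daf-7 higher and ugt-4 and lips-11 lower, limma-voom called 0 and 0, and the block called 0 and 1. Without RNAi replicate 2 edgeR called daf-7 (adjusted p = 1.67e-04).

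By camera with a preset correlation 11 lists were higher and 4 lower in the libraries labelled daf-7 RNAi, and none kept its call with an estimated correlation (adjusted p = 0.958 for each). None of the 15 kept its call and direction whichever single library was left out. The higher lists were cuticle collagens (median log2 0.54; col-19, 0.92 ± 0.39, adjusted p = 1), sperm genes (0.29), vitellogenins (0.20), muscle genes (0.18), proteasome (0.14), branched-chain amino acid degradation (0.12), the TCA cycle (0.10), intestinal genes (0.07), oxidative phosphorylation (0.07), autophagy and lysosome genes (0.01, below 0 with upper-quartile factors and library totals) and the dauer TGF-beta pathway (0.01, and -0.05 and -0.02 with those scalings; mean 0.48). Of the 7 TGF-beta genes only daf-7 passed adjusted over the list alone. The 4 lists called lower were neuropeptides (-0.10), nuclear hormone receptors (-0.05), insulin-like peptides (-0.06) and genes activated by DAF-16 (-0.14; ftn-1, a ferritin gene, -1.14 ± 0.40, adjusted p = 1). No member of these 15 lists passed over all genes tested, and none but daf-7 adjusted over the list alone. Collagens, sperm and muscle genes differed within neighbouring pairs mainly between libraries 11 and 12. From library 7 to library 12, in log2 units from the mean of the 12 libraries, collagens stood at 0.44, 0.58, -0.21, -0.21, 0.76 and 1.77, sperm genes at 1.76, 1.87, -0.15, -0.02, 0.44 and 1.33, and muscle genes at 0.85, 0.76, 0.09, 0.12, -0.03 and 0.61. Without daf-7 RNAi replicate 3 (library 12) the collagen median was -0.11 (adjusted p = 0.973) and the muscle median 0.11 (0.130), neither called, while the sperm median stayed at 0.29 (0.00693). Without vector replicate 2 (library 9) the sperm median was 0.02 (adjusted p = 0.396). With the block the insulin-like (adjusted p = 0.0594) and TGF-beta (adjusted p = 0.253) calls ended. The block added histones (adjusted p = 0.0163) among the lower lists, and glycolysis (0.0349), C-type lectins (0.0300) and germline genes (0.0357) among the higher ones. The count of lower lists was 2 without RNAi replicate 2, 11 without RNAi replicate 1, and 8, 7 and 9 without vector replicates 1, 2 and 3. That of higher lists was 6 without RNAi replicate 2.

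Whether the responses labelled bcat-1 and daf-7 RNAi resembled each other was asked across genes. The log2 fold changes correlated at a Pearson r of 0.0012 and a Spearman rho of -0.14 over 16618 genes, which are not independent replicates. The r of the mean log2 CPM differences was -0.10, and an exact permutation of the vector and RNAi labels within each strain gave a two-sided p of 0.65 (400 assignments, smallest possible p 0.01). That permutation ignores the neighbouring pairs. An exact permutation within the pairs, added after the results were seen, gave a p of 0.5625 (64 assignments, smallest possible p 0.0625, so that it could not pass 0.05). Of the 718 genes called in the bcat-1 comparison, 302 (42.1%) had the same sign in the daf-7 comparison. By edgeR 0 genes were called in both (1 by DESeq2, lips-11). Since edgeR called 0 genes in the daf-7 comparison, that overlap could not differ from 0 and says nothing about resemblance. The Pearson r moved to 0.18 and -0.17 without TU3311 vector replicates 1 and 2, to -0.20 and 0.14 without daf-7 RNAi replicates 1 and 2, and to -0.18 without bcat-1 RNAi replicate 2. The Spearman rho moved to 0.25 without TU3311 vector replicate 1 and to -0.38, 0.15 and 0.19 without daf-7 RNAi replicates 1, 2 and 3. Strain and RNAi target change together here, so neither can be named as what the responses share or lack.

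The test of the difference between the responses found genes that rose more in the libraries labelled bcat-1 RNAi, and they were genes that rose in daf-16(mu86). cpr-2 differed most (log2 5.69 ± 0.70, edgeR adjusted p = 0.00753). It rose in daf-16(mu86) and stood at 2.48 ± 1.32 and 0.770 ± 0.239 CPM on vector and in the libraries labelled daf-7 RNAi of TU3311. C05E7.3 (3.15 ± 0.39, adjusted p = 0.00753), nlp-66 (3.13 ± 0.49), C05C12.1 (3.10 ± 0.41) and C30A5.10 (3.05 ± 0.41) followed, and among C-type lectin genes clec-31 passed (2.88 ± 0.47, adjusted p = 0.0327). The 1 gene on the other side was F20A1.8 (log2 -3.48 ± 0.52, adjusted p = 0.0229), named here after its values were seen.

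By edgeR 17 genes were higher and 1 lower in this difference, and 2047 had an unadjusted p under 0.05. The block gave 2490 and 1859 with all 18 called genes kept, and leaving out libraries 7 and 8 gave 1264 and 923. The higher and lower counts were 0 and 0 without any 1 of the 3 daf-16(mu86) vector libraries, and 74 and 14 without TU3311 vector replicate 1. Without bcat-1 RNAi replicates 1, 2 and 3 they were 11 and 0, 5 and 0, and 6 and 1. They were 6 and 0 and 7 and 0 without TU3311 vector replicates 2 and 3, and 4 and 0 without daf-7 RNAi replicate 3, while without daf-7 RNAi replicate 2 the lower count was 2. By camera 5 lists lay higher and 15 lower in the difference, and none of the 20 kept its call with an estimated correlation (adjusted p = 0.549 to 0.658). The higher lists were neuropeptides (median 0.81), insulin-like peptides (0.90), synaptic genes (0.73), nuclear hormone receptors (0.57) and mitochondrially encoded genes (0.52). The 15 lists that lay lower included the proteasome (-0.59), germline (-0.67) and oocyte genes (-0.71), epidermal antimicrobial peptides (-1.37), the TOR pathway (-0.47), branched-chain amino acid degradation (-0.42), glycolysis (-0.40) and the heat shock response (-0.45; hsp-110, -0.94 ± 0.35, adjusted p = 0.299, with the block 0.0122). No member of these 20 lists passed over all genes tested, and adjusted over the list alone 2 insulin-like and 1 synaptic gene did. With the block, 38 neuropeptide, 59 receptor, 13 insulin-like, 13 synaptic and 1 mitochondrially encoded gene were higher, against 0, 3, 2, 1 and 0 lower. Lower with the block were 33 proteasome, 25 germline, 22 oocyte, 9 antimicrobial peptide, 6 TOR, 11 branched-chain amino acid, 11 glycolysis and 5 heat shock genes, against 1 TOR, 3 branched-chain amino acid and 1 heat shock gene higher. With 1 library left out the calls of the heat shock list (adjusted p = 0.213 without TU3311 vector replicate 2) and of the mitochondrially encoded list (0.132 without TU3311 vector replicate 3) could end. With the block the lipase list lost its call (adjusted p = 0.0688) and collagens (adjusted p = 0.00155), histones (0.0203) and DAF-16-activated genes (0.0216) were called higher, so that 8 lists lay higher, as also happened without library 7 or without library 8.

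The comparison of the vector groups asks how daf-16(mu86) differs from TU3311 without a target. Genes known to be activated by DAF-16 were among those that differed. Of 18 tested, 6 were lower in daf-16(mu86) and 14 adjusted over the list alone (median log2 -1.42). mtl-1, a metallothionein gene (WBGene00003473), was lower by -4.03 ± 0.49 (adjusted p = 0.00137), sod-3, a manganese superoxide dismutase gene, by -3.18 ± 0.47 (adjusted p = 0.00440), the ferritin gene ftn-1 by -2.36 ± 0.42 and hil-1 by -2.19 ± 0.31. dod-22, one of 12 genes known to be repressed by DAF-16, was higher at 15.3 ± 4.07 against 3.70 ± 0.641 CPM (SD, n = 3; 2.05 ± 0.27, adjusted p = 0.00192), while its list was not called (adjusted p = 0.409). haf-6, an ABC transporter gene, was higher at 26.2 ± 0.328 against 6.84 ± 0.334 CPM (1.94 ± 0.19, adjusted p = 4.26e-04), and T25B9.5 (2.33 ± 0.36), clec-74 (1.79 ± 0.43) and oac-20 (1.39 ± 0.34) were higher too.

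The largest falls were in genes near absence in daf-16(mu86). ugt-32 stood at 0.926 ± 0.553 against 62.7 ± 51.5 CPM (SD, n = 3; log2 -6.10 ± 0.76, adjusted p = 0.00153), col-183 at 0.271 ± 0.218 against 36.8 ± 33.5 CPM (-7.15 ± 1.14), F20E11.17 differed by -6.95 ± 1.12, and the secreted SCP-like genes scl-24 and scl-20 differed by -6.60 ± 0.90 and -6.40 ± 0.77. Of 62 UDP-glucuronosyltransferase genes 17 fell, and 33 adjusted over the list alone (median -0.89). Lysozymes and saposins (10 of 37; 18 adjusted over the list alone; median -0.82), cytochrome P450 genes (7 of 67; 20 fell and 3 rose adjusted over the list alone; median -0.83; cyp-35B1, -2.52 ± 0.47) and insulin-like peptides (5 of 32; 21 adjusted over the list alone; median -1.204; ins-22, -2.88 ± 0.36) fell as well. Tissue lists had lower medians as well, a list call that, like all 22 in this comparison, was not kept with an estimated correlation (adjusted p = 0.665 for each). They were muscle genes (5 of 25 fell, 18 adjusted over the list alone; unc-54, a myosin heavy chain gene, -1.85 ± 0.34), neuropeptides (5 of 55, 12 adjusted over the list alone; flp-8, -1.79 ± 0.30), synaptic genes (4 of 29; 13 fell and 1 rose adjusted over the list alone; unc-17, -1.37 ± 0.34), sperm genes (4 of 71; 23 fell and 1 rose adjusted over the list alone; gsp-4, -3.35 ± 0.89) and collagens (6 of 151, 5 adjusted over the list alone). Of 208 nuclear hormone receptor genes 6 fell (nhr-114, -1.51 ± 0.22), also adjusted over the list alone. Of 138 C-type lectin genes 12 fell and 2 rose (20 and 5 adjusted over the list alone). Library 7 (TU3311 vector replicate 1) stood apart from libraries 9 and 11 in these lists, with muscle genes at 0.85 against 0.09 and -0.03 log2 units from the mean of the 12 libraries, and sperm genes at 1.76 against -0.15 and 0.44. Without it the muscle median moved from -0.91 to -0.59 and the sperm median from -2.41 to -1.38, and the C-type lectin list was not called (median -0.36, adjusted p = 0.161).

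Lists that lay higher in daf-16(mu86) held almost no gene past the test. Among 81 cytosolic ribosomal protein genes (median log2 0.59; rpl-4, 0.69 ± 0.21, adjusted p = 0.0582) none passed over all genes, while 74 were higher and 1 lower adjusted over the list alone. The 30 germline genes (median 0.78) had 15 higher adjusted over the list alone. The proteasome (0.62), oocyte genes (0.85), oxidative phosphorylation (0.48), the mitochondrial unfolded protein response (0.56) and the TOR pathway (0.51) had none past either. Neither had the mitochondrially encoded genes, whose median of 0.28 turned to -0.02 with upper-quartile factors and whose call ended without daf-16(mu86) vector replicate 3 (adjusted p = 0.140). In the RNAi and small RNA list (median 0.52) rrf-2 was lower (-0.88 ± 0.25, adjusted p = 0.0493; 0 adjusted over the list alone), and in the TCA cycle list (0.45) idhg-2 was lower (-2.002 ± 0.34), also adjusted over the list alone. In the same TU3311 vector group, library 7 held less oocyte RNA than libraries 9 and 11, with list medians of -1.18, 0.05 and 0.07 log2 units from the mean of the 12 libraries, and more neuropeptide RNA, at 0.79, -0.15 and 0.08. In these libraries the proteasome list stood at -0.72, 0.03 and -0.07, oxidative phosphorylation at -0.64, -0.004 and -0.02 and RNAi genes at -0.75, 0.12 and -0.01. The differences of these 3 lists from daf-16(mu86) were thus larger against library 7 than against libraries 9 and 11.

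By edgeR 22 genes were higher and 1081 lower in daf-16(mu86), with 7326 at an unadjusted p under 0.05. Measures of whole libraries also differed between these vector groups without overlap. Genes with at least 10 counts numbered 13542 to 14693 in daf-16(mu86) and 15755 to 16726 in TU3311. Non-coding RNA held 0.104 to 0.134% and 0.177 to 0.319% of counts, and ribosomal RNA 0.106 to 0.293% and 1.28 to 3.18%. TMM factors were 0.863 to 0.899 and 0.960 to 1.16, while total counts overlapped. Without libraries 7 and 8 the counts were 2605 and 2589, and DESeq2 called 3145 higher. They were 4 and 52, 4 and 88, and 3 and 27 without daf-16(mu86) vector replicates 1, 2 and 3. Without TU3311 vector replicates 1, 2 and 3 they were 11 and 241, 41 and 1230, and 39 and 678. The library numbers 1 to 6 and 7 to 12 follow the strain, so strain and any batch cannot be told apart, neighbouring pairs give no block for this comparison, and the vector libraries of daf-16(mu86) also enter the bcat-1 comparison.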

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

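Chosen after the results were seen were the fits without libraries 7 and 8 and those of the 6 libraries with the block. The cause of the changes given here was not tested, unless the setting itself gives it. Leaving out libraries of another comparison can act only through the spread, expression filter and scaling factors that the fit shares. In the comparison labelled bcat-1 RNAi, 694 genes were higher. They were 297 with RLE factors, 1136 with library totals, 462 without a filter, 195 with the filter of 10 CPM, 3628 with only the 6 libraries, 3848 with these and the block, 265 on log2(RPKM + 1) without a filter, and 3455 without libraries 7 and 8. The replicate block gave 4275. Leaving out 1 library gave 42 to 319. The 24 lower genes became 228 with DESeq2, 15 with upper-quartile factors, 14 with library totals, 2488 with only the 6 libraries, 2559 with these and the block, 8, 13 and 2 on log2(RPKM + 1), log2(RPKM + 0.1) and log2(RPKM + 1) without a filter, and 2441 without libraries 7 and 8. The replicate block gave 3081, and leaving out 1 library gave 3 to 8. Of the 718 called genes 703 were kept with only the 6 libraries. The share of higher genes among the calls, 96.7%, ran from 90% to 98.8% over the scalings, which were run only in the fit of all libraries without the block.

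In the comparison labelled daf-7 RNAi, the 0 higher genes by edgeR (77 genes in both directions at an unadjusted p under 0.05) became 1 with DESeq2, 1 with RLE factors, 1 without a filter and 1 on log2(RPKM + 1) without a filter, and 0 to 1 when 1 library was left out. The 0 lower genes became 2 with DESeq2, 3 on log2(RPKM + 1) without a filter, 1 with the replicate block and 1 without libraries 7 and 8, and were 0 with only the 6 libraries and the block and when any 1 library was left out. limma-voom called 0 in both directions.

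In the strain comparison, the 22 higher genes became 3145 with DESeq2, 12 with limma-voom, 14 with RLE factors, 81 with upper-quartile factors, 108 without a filter, 5 with the filter of 10 CPM, 14 with only the 6 libraries, 4, 4 and 2 on the 3 RPKM settings, 2605 without libraries 7 and 8, and 3 to 41 when 1 library was left out. The 1081 lower genes became 486 with limma-voom, 242 with RLE factors, 1816 with upper-quartile factors, 2858 with library totals, 83 with the filter of 10 CPM, 512 with only the 6 libraries, 1701, 2322 and 54 on the RPKM settings, 2589 without libraries 7 and 8, and 27 to 1230 when 1 library was left out. With only the 6 libraries 464 of the 1103 called genes were kept. No paired analysis was possible for this comparison because the pairs lie within strains.

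In the difference between the responses, the 17 higher genes became 105 with DESeq2, 11 with RLE factors, 2 with upper-quartile factors, 27 with library totals, 36 without a filter, 0 with the filter of 10 CPM, 98 and 159 on log2(RPKM + 1) and log2(RPKM + 0.1), 1264 without libraries 7 and 8, 2490 with the replicate block, and 0 to 74 when 1 library was left out. The 1 lower gene became 23 with DESeq2, 0 with upper-quartile factors, 0 with library totals, 4 without a filter, 0 with the filter of 10 CPM, 0 and 0 on the same RPKM settings, 923 without libraries 7 and 8, 1859 with the replicate block, and 0 to 14 when 1 library was left out. The fit with only 6 libraries was not run for the difference, which needs all 12.

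Calls of gene lists moved with the assumed correlation. With an estimated correlation the higher and lower lists were 0 and 0 in all 4 comparisons. By fry they were 0 and 0, but for 1 and 2 in the strain comparison; fry asks whether a list moves, not whether it moves more than other genes. In the comparison labelled daf-7 RNAi the 11 higher lists became 7 with RLE factors and 7 with only the 6 libraries, and 6 to 15 when 1 library was left out, while the 4 lower lists became 2 to 11. In the difference the 5 higher lists became 8 with the replicate block and 4 to 8 when 1 library was left out. The other counts of lists stayed within 1.5 times under the settings run. Beyond the values given here and in the report, the block changed no other call of a list, and no named gene lost its call with it.

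The Pearson correlation of the responses, 0.0012, moved to -0.15 with the filter of 10 CPM, to -0.20 on log2(RPKM + 1), to -0.14 over genes called in either comparison, and to between -0.20 and 0.18 when 1 library was left out. The Spearman correlation of -0.14 moved to -0.37 with the filter of 10 CPM and to between -0.38 and 0.25 when 1 library was left out. DESeq2 called 1 gene in both comparisons, and leaving out 1 library gave 0, with only 0 to 1 genes called in the comparison labelled daf-7 RNAi. The totals of 30130249 to 45343624 counts limit genes of low level, which the filter left out, and the edgeR fit recovered no simulated 1.5-fold change.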

Other observations

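The tests of scaling, of the germline share, of embryos, of exchanged labels and of a culture shared by neighbouring numbers, the fits without libraries 7 and 8, and the margin asked of the test of genomic DNA, were chosen after the results they measure were seen. lips-11, a lipase-family gene, was lower in the library labelled RNAi in each of the 3 neighbouring pairs of both comparisons. In daf-16(mu86) it stood at 55.7 CPM on vector and 21.1 CPM in the libraries labelled bcat-1 RNAi (log2 -1.402 ± 0.48, edgeR adjusted p = 0.114; with the block 3.07e-04). It was singled out here after its values were seen. The test of the difference between the responses gave 0.86 ± 0.67 (adjusted p = 0.611). By DESeq2 it was called in both comparisons (log2 -1.61, adjusted p = 0.0117, and -2.28, adjusted p = 0.00256).

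The genes called higher in the libraries labelled bcat-1 RNAi rose by a median log2 of 1.504. Reads from genomic DNA or unspliced RNA would raise silent loci as much, and counts at piRNA loci rose by 1.03 ± 0.22 (SE). That rise plus 2 standard errors is 1.47, but the called genes were chosen for their rise, so a median just above it does not argue against such reads, and they stay open. The higher numbers of genes with at least 10 counts in these libraries, 15468 to 16028 against 13542 to 14693, do not separate such reads from a response. Within the main fit, scaling is argued against as the whole cause of the larger number of higher genes. RLE factors, with a median change of all genes of -0.04, gave 297 higher genes in place of 694. Yet 90% of the genes called with them were higher (33 lower), the lowest share over 3 other scalings. Upper-quartile factors and library totals moved the median change of all genes up, to 0.31 and 0.36, so the argument rests on RLE factors alone. The imbalance of higher over lower genes depended on the fit, with 4275 higher and 3081 lower with the block and 3628 and 2488 with only the 6 libraries. Other scalings were not run with these 2 fits, so the test does not cover them. A lower germline share would raise the other tissues alike. Neuropeptides (median 0.67) and vitellogenins (-0.21) lay 0.881 apart, beyond the larger interquartile range of 0.241. With each library left out the excess was at least 0.474. This was the largest excess among all pairs of the muscle, neuropeptide, synaptic, collagen, intestinal and vitellogenin lists, which thus did not rise alike. The 6 vitellogenins also lay 0.454 below the intestinal genes (larger interquartile range 0.36), but without library 2 that gap was 0.342 against 0.39. A change of the vitellogenins by themselves would give both gaps. It would not give the 0.427 by which neuropeptides lay above the intestinal genes (larger interquartile range 0.36). Without library 2 this was 0.573 against 0.39, and without library 4 it was 0.536 against 0.324. For these lists the gaps argue against a lower germline share as the whole cause, while it stays open as a part. Embryos held in the adults may still add to the rise: 0 of 44 embryonic genes were called against 4.19% of the other genes (two-sided Fisher exact p = 0.263), and a response to bcat-1 RNAi also stays open as the biological explanation.

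Counts of both target genes were higher in the libraries labelled with their RNAi. If vector and RNAi labels were exchanged in both strains, the libraries labelled daf-7 RNAi would hold the daf-7 level of untreated animals. Their lowest value lay 27.6 CPM above the highest of the 6 daf-16(mu86) libraries, but the strains differ in daf-7 on vector, so this does not decide. Reads from the fed double-stranded RNA could give the excess, which was 85.6 CPM for daf-7 and 59.4 CPM for bcat-1, and counts per exon, which would tell, were not used here. Exchanged labels, reads of the fed RNA and a true rise of the transcripts cannot be told apart.

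Libraries 7 and 8 lay apart from the other 4 TU3311 libraries, with 2267 genes above and 1753 below them by over 1 log2 unit. Oocyte genes were lower by a median of -1.33 and germline genes by -1.18, while vitellogenins (0.99), neuropeptides (0.94), sperm genes (1.43) and muscle genes (0.59) were higher. Intestinal genes had a median of 0.63 (interquartile range 0.99) and cuticle collagens one of 0.07 (interquartile range 0.97). A lower germline share would raise the other tissues alike. Muscle genes lay 0.351 below neuropeptides and 0.402 below vitellogenins, beyond the larger interquartile range of 0.237, which would go against it as the whole cause. But the first gap ended without library 12 (0.128 against 0.173, an excess of -0.0455) and the second without library 8 (0.319 against 0.372), so the share stays open. A culture or preparation shared by neighbouring numbers stays open as well. The deviations of the 6 pairs, with a lowest correlation of 0.158, do not exclude it, but they are the values that prompted it and so do not test it. No biological explanation was tested, since both libraries come from different groups of the design.

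Other groupings of the libraries were counted for each comparison. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. In the comparison labelled bcat-1 RNAi the real split gave 694 higher genes and the highest other split 0, so that 1 of the 10 gave as many. In the strain comparison the real split gave 1103 calls and the highest other 0, so again 1. In the comparison labelled daf-7 RNAi the real split gave 0 calls, which all 10 reach, and the highest other, of libraries 7, 8 and 11 against the rest, gave 3708, which points to a structure of the samples. In the difference the real split gave 18 calls, and 8 of 100 drawn splits gave as many, up to 5292. The 7 others all part libraries 1, 3 and 5 from 2, 4 and 6 as the real split does and regroup only TU3311, so they keep the response labelled bcat-1 RNAi, while drawn splits that regroup daf-16(mu86) gave 0. The 7 show how far the TU3311 grouping moves the count, and chance is not excluded. Drawn splits that part all 6 pairs as the real one does gave at most 13, while those with more calls part 4.

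The deposited RPKM values used 36 per-million factors in turn down the genes. Of these, 12 equalled totals of these libraries within 0.01% and 24 matched none of them, and the highest factor was 1.78 times the lowest.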
